A study of Mus musculus with 5 samples.

How the data were processed

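RNA was measured in mouse forelimb buds at 2 stages of embryonic development, E10.5 and E11.5. The E11.5 tissue was the micro-dissected distal part of the bud, where the digits arise, taken from wild-type embryos and from embryos homozygous for loss-of-function alleles of both Hoxa13 and Hoxd13. Per the labels' protocols, the RNA of each E11.5 genotype came from 2 independent pools of dissected tissue, with N = 4 given for the tissue samples, without saying whether per pool. The pools were separate, so the 2 libraries of a genotype were treated as biological replicates. The E10.5 group had 1 library. The strain label was CD1 for the E10.5 library and a mixed C57BL/6 and CD1 background for the E11.5 libraries, so stage, dissected part and strain label all changed together between E10.5 and E11.5. Whether mutant and wild-type pools differed in strain make-up within the mixed background was not tested.

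Per the labels' protocols, ribosomal RNA was depleted with Ribo-Zero, strand-specific libraries were made with the TruSeq stranded total RNA kit and 8 cycles of PCR, and both ends were sequenced for 50 cycles. Per the submitters' processing notes, the tools were TopHat2 2.0.13, Cufflinks 2.1.1, HTSeq and SAMtools, with the mm9 genome. The deposited values were whole-number counts of reads per gene symbol, made by the authors with HTSeq. The strand setting of HTSeq, its annotation and its filters were not given in the sources used here. Genes that overlap or lie antisense to another gene, such as Hoxa11as opposite Hoxa11, are therefore reported as uncertain. Genes with near-identical copies, such as replication-dependent histone genes and globins, are uncertain as well.

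Each table held 23284 gene symbols and 5 HTSeq total lines, and the latter were left out of library sizes and tests. Reads assigned to no feature made up 24.3% of the lines' sum at E10.5, 34.4% and 39.6% in mutant replicates 1 and 2, and 39.2% and 30.3% in wild-type replicates 1 and 2. Reads without a unique alignment made up 14.8%, 10.3%, 9.1%, 10.6% and 14.2% in the same order, and ambiguous reads 1.1%, 0.9%, 0.8%, 0.8% and 0.8%. Symbols were matched to a RefSeq gene table of the GRCm38.p6 assembly, used only for names and for the order of neighbouring genes. A current name matched for 20683 symbols, an older name for 2355 and none for 246. Coordinates are not printed, because the assembly differs from mm9.

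The main comparison was mutant against wild type at E11.5, with the 4 E11.5 libraries in the fit and genotype as the only term. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled with TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene is said to have risen or fallen at an adjusted p below 0.05. The installed edgeR uses its older quasi-likelihood estimate by default. That estimate had been listed as the alternative, so the newer estimate was run as an added alternative instead. Means are CPM (counts scaled to library size) with the SD over 2 libraries, and standard errors (SE) belong to the log2 fold change. Fold changes are mutant over wild type, so a negative log2 value is lower in the mutant.

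There were 27 gene lists with 459 distinct genes, fixed before the data were examined. They covered the HoxA cluster, the HoxD cluster and its flank, the HoxB and HoxC clusters, early and proximal limb bud, distal limb bud and autopod, HOX13 targets in the literature, Eph receptors and ephrins, and the hedgehog, FGF, BMP, WNT and retinoic acid pathways. Further lists held genes of chondrogenesis, tendon and connective tissue, apical ectodermal ridge, surface ectoderm, muscle lineage, endothelium, erythroid cells, macrophages, neurons and Schwann cell lineage, and body wall and somite tissue. The last group held cell cycle, p53 response and cell death, immediate early and heat shock genes, hypoxia and glycolysis, and sex-linked genes. Of the listed symbols 3 matched no symbol in the tables (Ahsp, Hotair and Hottip). Lists with at least 3 measured genes were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Some genes stand in several lists.

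The E10.5 library has no replicate, so its comparison with wild-type E11.5 has no p-value. A gene was called higher or lower when the E10.5 value differed at least 2-fold, in the same direction, from each of the 2 wild-type libraries, on log2 TMM-scaled CPM with a prior count of 2. For each list the median difference was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. The overlap of both comparisons was set beside the number that independent lists would give and beside 20 simulations of unchanged groups against simulated wild-type libraries shared by both comparisons. The comparisons with E10.5 scale the 5 libraries together, so their means differ slightly from those of the 4 E11.5 libraries. A fold against libraries with no count is a lower bound computed from 3 counts in each such library. A ratio resting on 1 to 3 counts carries an exact 95% interval. Such bounds and intervals cover counting error only.

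Named genes followed a rule fixed with the lists. Hoxa13 and Hoxd13 came first. Among genes past the threshold, with both mutant libraries beyond both wild-type libraries and a mean of at least 1 CPM, the 12 with the largest and the 12 with the lowest log2 fold change were named, passing over gene models and small RNAs. Of each list up to 4 members of smallest adjusted p were named. At E10.5 the 8 genes per side with the largest difference were named among genes of at least 5 CPM in the E10.5 library or in both wild-type libraries, and of the overlap up to 8 genes per direction by adjusted p. Genes named outside this rule are said to be so. A few list members that the rule would name are not reported here.

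Counts were simulated from the real means and the trend of spread with expression level, not from each gene's own spread. Genes varied independently and followed the model of the test, so the rates below may be optimistic. On these counts (16011 genes, 200 of them changed), the mutant test recovered 59.7% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 98.5% of those changed 4-fold. It made 169 calls, of which 10 were false. DESeq2 made 157 calls there. The E10.5 rule, on 16416 simulated genes, recovered 97.5% of 200 genes changed 4-fold and took 71 of 16216 unchanged genes (0.44%). For this rule the lone E10.5 library was assumed to vary like the others. Replicates were not copies of one library: the chi-square per degree of freedom was 12.5 for the mutant pair and 29.9 for the wild-type pair.

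The alternatives were DESeq2 1.42.0, DESeq2's size factors, upper-quartile factors, library totals, other filters, a robust fit, all 5 libraries in the fit, libraries thinned to the shallowest total, the replicate number as a block, other prior counts and fold limits, and leaving out each E11.5 library in turn. Where that left 1 library in a genotype, the lone library was assumed to vary like the other genotype's pair.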

Results

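Total RNA was profiled in 5 mouse forelimb libraries. There was 1 library of E10.5 forelimb bud. There were 2 of E11.5 distal forelimb from wild-type embryos and 2 of E11.5 distal forelimb from Hoxa13-/-;Hoxd13-/- embryos, called mutant here. Reads counted in genes totalled 84172202 at E10.5, 59837137 and 48303512 in mutant replicates 1 and 2, and 45115494 and 55842997 in wild-type replicates 1 and 2. Between 18039 and 18415 genes had a count in each library. Hoxa13 and Hoxd13 encode homeodomain transcription factors of the region that forms the digits, and the series title poses the question of what HOX13 activity does during digit development.

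The targeted genes were examined first. Hoxd13 fell from 248 ± 5.85 CPM (SD, n = 2) in wild type to 43.6 ± 5.53 in the mutant, a log2 fold change of -2.50 (SE 0.10, adjusted p = 1.12e-07 by the edgeR quasi-likelihood test). Both mutant libraries (47.5 and 39.7) lay below both wild-type libraries (244 and 252). Hoxa13 measured 43.7 ± 5.89 CPM in the mutant and 49.2 ± 1.25 in wild type (log2 fold change -0.17, SE 0.11, adjusted p = 0.438). Its log2 fold change was -0.32 without mutant replicate 1 and -0.04 without mutant replicate 2. Both alleles are insertions, a neomycin cassette in the coding region of Hoxa13 and lacZ in the first exon of Hoxd13, and reads elsewhere in the transcript can remain. The Hoxa13 level therefore does not check the labels.

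Around the targeted genes, many anterior and central HoxA and HoxD genes rose in the mutant, and Hoxd13 and its flanking neighbours Evx2 and Lnp fell. Of 11 measured genes of the HoxD cluster and its flank, 6 rose and 3 fell (6 and 4 adjusted over the list alone). Hoxd4 rose from 12.5 ± 0.914 to 51.3 ± 3.40 CPM (log2 fold change 2.04, SE 0.11, adjusted p = 5.92e-07) and Hoxd8 from 14.7 ± 3.04 to 50.1 ± 4.15 (1.77, SE 0.14). Evx2, the homeobox gene next to Hoxd13, fell from 10.6 ± 0.603 to 0.463 ± 0.0424 CPM (-4.52, SE 0.22, adjusted p = 2.78e-07). Hoxd3 (2.12), Hoxd9 (1.54), Hoxd10 (0.82) and Hoxd11 (0.60) also rose, and Lnp, in the flank beyond Evx2, fell (-1.02). Hoxd12 had -0.36 with an adjusted p of 0.119. Hoxd3, Hoxd10, Hoxd11, Hoxd12 and Lnp were named after their values were seen. In the HoxA cluster 6 of 13 genes rose and 1 fell (8 and 1 adjusted over the list alone). Hoxa11, a gene of the forearm region, rose from 55.7 ± 7.97 to 114 ± 19.2 CPM (1.04, SE 0.13, adjusted p = 0.000349), and Evx1 (1.30), Hoxa5 (1.07) and Hoxa7 (1.04) rose as well. The gene that fell was Hoxa11as, antisense to Hoxa11 (-0.48, named after its value was seen). The values of Hoxa11as and Hoxa11 are uncertain because the strand setting of the counting is not given in the sources used here. Of 14 genes of the HoxB and HoxC clusters 2 rose and 0 fell (4 and 0 adjusted over the list alone), namely Hoxc11 (3.27, SE 0.48) and Hoxb9 (2.48, SE 0.36). The camera test called HoxA (up, adjusted p = 8.63e-06) and HoxB with HoxC (up, adjusted p = 0.0168), but not HoxD (adjusted p = 0.369). With an estimated correlation the adjusted p was 0.67, 0.67 and 0.736. The HoxB and HoxC call ended without mutant replicate 1 (adjusted p = 0.0696) or wild-type replicate 2 (0.104), and a HoxD call appeared without mutant replicate 2 (0.00383). The Hoxc11 log2 fold change was 4.62 without wild-type replicate 1 and 2.52 without wild-type replicate 2.

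**Figure D1:**
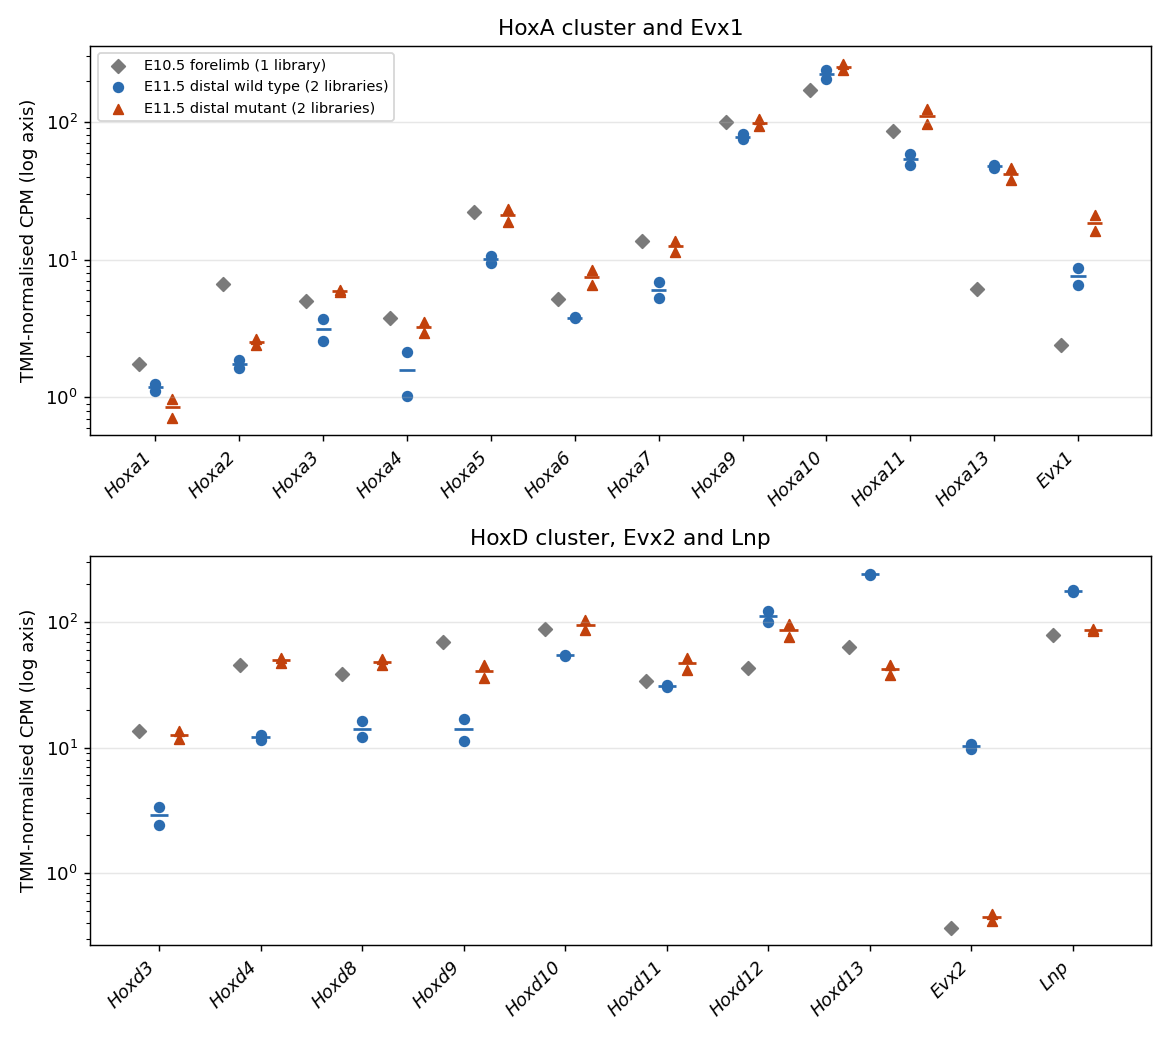
TMM-normalised CPM on a log axis of genes of the HoxA cluster (top) and of the HoxD cluster with Evx2 and Lnp (bottom), with a symbol for each library and a bar at the mean of each E11.5 pair. Hoxd13, Evx2 and Lnp lay lower in the mutant than in wild type, and Hoxd3 to Hoxd11 lay higher.

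Across the transcriptome 617 genes rose and 540 fell in the mutant among 16166 tested, which is 7.2% of them, and 253 and 193 of these changed at least 2-fold. The largest rise by the naming rule was that of Styk1, which encodes a kinase-like protein and had 550 counts in the mutant libraries against 2 in wild type, a ratio of 253 with an exact 95% interval of 69.6 to 2090. Fgf4, a growth factor of the apical ectodermal ridge, rose from 0.435 ± 0.0965 to 7.20 ± 0.186 CPM (log2 fold change 4.06, SE 0.25, adjusted p = 1.79e-06). The others on this side were Wdr65 (3.86), Hfm1, a meiotic DNA helicase (3.50), Ppp2r2c, a phosphatase subunit (3.43), Cytl1, a secreted cytokine-like protein (3.41), and Trim12a (3.33). Further down came Hoxc11, Elmod1 (3.25), Col6a5, a collagen VI chain (3.23), Crhbp, the binding protein of corticotropin-releasing hormone (3.03), and Fbxo44 (3.0). Cntnap3, a cell adhesion molecule, fell from 3.02 ± 0.160 to 0.0745 ± 0.0110 CPM (-5.31, SE 0.39, adjusted p = 7.58e-06). Eomes, a T-box transcription factor, fell from 6.01 ± 2.37 to 0.323 ± 0.00862 (-4.21, SE 0.34). Also on this side were Evx2, the chondrogenic transcription factor Nkx3-2 (-3.70), Sorcs1, a sorting receptor (-3.49), and Cbln4, a secreted cerebellin (-3.45). They were followed by the homeobox gene Irx1 (-3.10), the connexin gene Gja3 (-3.05), Wdr72 (-2.96), Sv2b, a synaptic vesicle protein (-2.86), Hoxd13 and Gchfr, a regulator of GTP cyclohydrolase (-2.48). Without wild-type replicate 1 the number of changed genes was 2018 in place of 1157. The log2 fold change of Wdr65 was 5.36 and that of Crhbp 3.95 without wild-type replicate 2. That of Nkx3-2 was -5.62 without mutant replicate 1 and -2.996 without mutant replicate 2. Wdr65 had 3.22 without wild-type replicate 1. Styk1 had 6.79 without wild-type replicate 2 and no wild-type count without wild-type replicate 1.

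Genes of the distal limb bud fell more often than they rose. In the list of distal limb bud and autopod genes 8 of 26 fell and 3 rose (10 and 6 adjusted over the list alone). Evx2, the neighbour of the targeted Hoxd13, was a fallen member and had the largest change of the list (-4.52). The list was not tested without Evx2. Camera called the distal list down (adjusted p = 1.62e-05, median log2 fold change -0.16, 17 of 26 below 0), with an adjusted p of 0.67 with an estimated correlation. The median was -0.03 without wild-type replicate 1 and -0.28 without wild-type replicate 2. Jag1, a Notch ligand, fell from 170 ± 8.12 to 44.5 ± 4.89 CPM (-1.93, SE 0.10, adjusted p = 4.38e-07), and the transcription factor gene Tfap2b fell from 42.2 ± 6.34 to 18.4 ± 0.0666 (-1.19, SE 0.12). Sall3, a zinc finger transcription factor, rose from 9.22 ± 2.70 to 24.6 ± 2.30 CPM (1.42, SE 0.17, adjusted p = 0.000349). Among early and proximal limb bud genes 4 of 20 rose and 0 fell (4 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.115; 0.67 with an estimated correlation). Among them were Hoxd9, Hoxa11, whose value is uncertain as said above, and Zbtb16, a zinc finger gene of limb patterning (0.98). Meis1, Meis2, Irx3 and Pkdcc, named after their values were seen, had log2 fold changes of -0.13, -0.04, 0.33 and -0.11 with adjusted p of 0.744, 0.942, 0.716 and 0.901. A call of this list appeared without wild-type replicate 1 (0.0262). Of 21 genes named as HOX13 targets in the literature 3 rose and 5 fell (4 and 5 adjusted over the list alone). The camera adjusted p was 0.778, in the downward direction, and 0.837 with an estimated correlation, with a median of -0.07 and a mean of 0.03. Gli3, the transcription factor that restrains hedgehog signalling, rose from 121 ± 5.84 to 207 ± 1.74 CPM (0.77, SE 0.08), and Enpp2, which makes lysophosphatidic acid, rose (1.06). Shh, the posterior limb signal, rose from 1.77 ± 0.188 to 6.50 ± 1.31 (1.87, SE 0.22, adjusted p = 0.000284), while Dach1, a transcriptional cofactor, fell (-0.92). Of 21 Eph receptors and ephrins, cell contact signals, Epha3 rose (0.61) and Epha5 (-0.99) and Efna1 (-0.78) fell, the same 1 and 2 adjusted over the list alone (camera adjusted p = 0.887; 0.945 with an estimated correlation).

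Several signalling pathways changed in part. In the hedgehog list 4 of 18 genes rose and 2 fell (5 and 2 adjusted over the list alone). The hedgehog median was 0.10, with 0.23 without wild-type replicate 1 and 0.05 without wild-type replicate 2. Shh, Gli3, the BMP antagonist Grem1 (0.72, from 38.4 ± 0.159 to 63.1 ± 3.21 CPM) and the co-receptor Boc (0.72) were the 4 of smallest adjusted p. Ptch1, a direct readout of the pathway, was named after its value was seen and had 0.28 with an adjusted p of 0.375. The ridge list had 3 risen and 2 fallen of 14 (3 and 2 adjusted over the list alone). Fgf4, Fgf8 (1.06, from 10.4 ± 1.48 to 21.6 ± 0.774 CPM) and Fgf17 (1.42) rose. The transcription factor genes Sp6 (-0.81) and Dlx2 (-1.48) fell, and Dlx2 was named after its value was seen. In the FGF pathway 3 of 17 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.452, and 0.759 with an estimated correlation). Dusp6, a phosphatase induced by FGF signalling, rose from 284 ± 25.3 to 481 ± 27.4 CPM (0.76, SE 0.09) and the inhibitor Il17rd rose (0.55), while the ligand Fgf10 (-0.68) and the receptor Fgfr2 (-0.44) fell. In the BMP pathway 7 of 23 fell and 3 rose (9 and 5 adjusted over the list alone). Id1, a target of BMP signalling, fell from 232 ± 15 to 138 ± 4.52 CPM (-0.75, SE 0.09, adjusted p = 0.000246). Msx1 (-0.84) and Msx2 (-0.93), homeobox genes that respond to BMP, fell, and the ligand Bmp5 rose (0.88).

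Camera called the hedgehog list up (adjusted p = 0.0168), the ridge list up (0.0425) and the BMP list down (0.0326), and with an estimated correlation each had an adjusted p of 0.67. The hedgehog (adjusted p = 0.201) and ridge (0.314) calls ended without mutant replicate 1, as did those of Fgfr2 (0.105) and Fgf17 (0.068). The BMP call ended without mutant replicate 2 (0.172), and all 3 ended without wild-type replicate 2 (hedgehog 0.244, ridge 0.252, BMP 0.104). In the WNT pathway 3 of 25 genes rose and 3 fell, the same numbers adjusted over the list alone. The secreted WNT antagonist Frzb (0.76) and the WNT deacylase Notum (0.85) rose, and the ligand Wnt11 (-0.95) and the receptor Lgr5 (-1.06) fell. The WNT median (-0.02) and mean (0.06) differed in sign, and the camera adjusted p was 0.748, in the upward direction, or 0.849 with an estimated correlation. In the retinoic acid pathway 3 of 16 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.369, and 0.67 with an estimated correlation). The retinaldehyde reductase Dhrs3 rose (1.10), and the retinoic acid hydroxylase Cyp26a1 (-1.19) and the synthesising enzyme Aldh1a2 (-0.86, from 36.4 ± 3.29 to 20.1 ± 2.98 CPM) fell.

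In the skeletal and connective tissue lineages a few single genes changed, and neither list was called. In chondrogenesis 1 of 27 genes rose and 2 fell (4 and 2 adjusted over the list alone). Col9a1, a cartilage collagen, rose (0.45), and Nkx3-2 (-3.70) and the matrix protein Matn4 (-0.88) fell. Sox9, the master regulator of cartilage, was named after its value was seen and had 0.36 with an adjusted p of 0.193. The chondrogenesis median (0.14) and mean (-0.06) differed in sign, and the camera adjusted p was 0.419, upward, or 0.809 with an estimated correlation. In tendon and connective tissue Col1a1 (1.02) and Col1a2 (0.48), the chains of collagen I, rose and 0 of 16 fell (4 and 2 adjusted over the list alone). The tendon list had a camera adjusted p of 0.698, upward, and 0.775 with an estimated correlation, beside a median of -0.000789 and a mean of 0.01. The log2 fold change of Nkx3-2 was -5.62 without mutant replicate 1 and -2.996 without mutant replicate 2. The adjusted p without mutant replicate 1 was 0.0544 for Col9a1, 0.110 for Matn4 and 0.133 for Col1a2. Matn4 had 0.0535 without wild-type replicate 1, and DESeq2 gave Col1a1 0.103. A chondrogenesis call appeared without wild-type replicate 1 (0.0326), where 8 genes rose and 1 fell. The chondrogenesis median was 0.26 in that fit and 0.05 without wild-type replicate 2. The log2 fold change of Col9a1 was 0.27 without wild-type replicate 1, and that of Col1a1 was 0.67 without wild-type replicate 2.

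Markers of the other cell types of the limb changed in both directions. Neuronal genes were lower: Tubb3, a neuronal tubulin, fell from 25 ± 3.15 to 8.58 ± 0.538 CPM (-1.54, SE 0.13, adjusted p = 2.64e-05) and Stmn2, a neuronal growth cone protein, from 8.45 ± 1.66 to 2.85 ± 0.621 (-1.57, SE 0.21). These were the 2 of 14 neuron and Schwann cell genes that fell, with 0 risen (2 and 0 adjusted over the list alone). Camera called the list down (adjusted p = 0.0016; 0.67 with an estimated correlation). In muscle 1 of 17 genes fell and 0 rose (4 and 0 adjusted over the list alone), namely cardiac actin Actc1 (-0.87), and the list was called down (0.0299; 0.736 with an estimated correlation). The muscle median was -0.29, with -0.09 without mutant replicate 1 and -0.51 without mutant replicate 2. Among erythroid genes the embryonic globin Hbb-bh1 rose from 359 ± 10.54 to 628 ± 11.4 CPM (0.81, SE 0.08), 1 of 11 with 0 fallen (4 and 0 adjusted over the list alone), and the list was called up (0.0047; 0.67 with an estimated correlation). The globin gene Beta-s, outside the list, fell (-1.64, SE 0.10). The macrophage genes Lyz2 (1.19) and Mrc1 (0.62) rose, 2 of 14 with 0 fallen, as adjusted over the list alone, and the list was called up (0.0326; 0.67 with an estimated correlation). In endothelium the receptor genes Flt1 (0.69) and Gpr116 (0.41) rose and the transcription factor gene Erg fell (-0.54), 2 and 1 of 18 (5 and 1 adjusted over the list alone; camera adjusted p = 0.107, and 0.736 with an estimated correlation). In surface ectoderm 3 of 21 fell and 0 rose (5 and 0 adjusted over the list alone; 0.115, and 0.67 with an estimated correlation), among them the keratins Krt8 (-0.56) and Krt14 (-0.42). In body wall and somite tissue Gata6 rose (2.09) and Foxc2 fell (-1.19) among 10 genes (4 and 2 adjusted over the list alone; 0.419, and 0.736 with an estimated correlation). The macrophage (0.0696) and muscle (0.314) calls ended without mutant replicate 1, the macrophage call also without wild-type replicate 1 (0.286) and the muscle call without wild-type replicate 2 (0.172). Calls of endothelium (0.00698) and surface ectoderm (0.0323) appeared without mutant replicate 2. Without mutant replicate 1 the adjusted p was 0.344 for Flt1, 0.384 for Gpr116, 0.090 for Krt8, 0.316 for Krt14 and 0.089 for Foxc2. Without mutant replicate 2 it was 0.0745 for Erg, 0.0768 for Gpr116 and 0.139 for Foxc2. Leaving out wild-type replicate 1 gave 0.0636 for Gpr116, and leaving out wild-type replicate 2 gave 0.060 for Flt1, 0.0558 for Krt8, 0.0666 for Krt14 and 0.0773 for Foxc2. DESeq2 gave Foxc2 0.0567, and with DESeq2's size factors Gpr116 had 0.051. The log2 fold change of Flt1 was 0.43 without mutant replicate 1, and that of Mrc1 was 0.36 without wild-type replicate 1 and 0.93 without wild-type replicate 2.

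Genes of glycolysis and the hypoxia response were higher in the mutant. In that list 6 of 20 rose and 0 fell (8 and 0 adjusted over the list alone). Camera called it up (adjusted p = 5.74e-05, median 0.34, 17 of 20 above 0; 0.67 with an estimated correlation). Pdk1, which limits the entry of pyruvate into mitochondria, rose from 75.1 ± 8.22 to 152 ± 45.3 CPM (1.02, SE 0.16, adjusted p = 0.00199). The glycolytic enzyme genes Pfkl (0.78) and Pgk1 (0.68) rose, and so did Bnip3, a gene of mitochondrial removal (0.88). When mutant replicate 1 was left out, the list median was 0.13 with an adjusted p of 0.0696 and 2 members rose. In that fit the log2 fold change was 0.42 for Pgk1 (adjusted p = 0.143), 0.44 for Bnip3 (0.068), 0.68 for Pdk1 and 0.49 for Pfkl. DESeq2 gave Bnip3 an adjusted p of 0.209. Without mutant replicate 2 the list median was 0.54 and 9 members rose. Immediate early and heat shock genes were called down (adjusted p = 0.0168, median -0.31; 0.67 with an estimated correlation), with 3 of 20 fallen and 1 risen (5 and 1 adjusted over the list alone). Their median was -0.21 without wild-type replicate 2. Gadd45b, a stress response gene (-0.68), and the chaperone gene Dnajb1 (-0.41) fell and Ier2 rose (0.50). Fosb fell as well, with 2 counts in the mutant libraries together against 29 in wild type, a wild-type to mutant ratio of 15.8 with an exact 95% interval of 3.99 to 136. Both mutant counts lay in replicate 1, and without mutant replicate 2 the Fosb log2 fold change was -3.04. Among cell cycle genes Ccnd1 rose (0.38) and Ccnd2 fell (-0.46), both D-type cyclins and 1 each of 28, as adjusted over the list alone (camera adjusted p = 0.133; 0.736 with an estimated correlation). In the p53 and cell death list Pmaip1, which promotes apoptosis, rose (0.65, from 131 ± 2.64 to 205 ± 10.7 CPM), 1 of 17 with 0 fallen (2 and 0 adjusted over the list alone). The list had a median of -0.06, a mean of 0.03 and a camera adjusted p of 0.748, upward, or 0.837 with an estimated correlation. Of 5 sex-linked genes the Y-linked demethylase gene Kdm5d rose (0.36) and 0 fell, as adjusted over the list alone (0.748; 0.837 with an estimated correlation). Leaving out mutant replicate 1 gave adjusted p of 0.150 for Gadd45b, 0.131 for Ier2, 0.0809 for Ccnd2, 0.286 for Ccnd1 and 0.179 for Kdm5d. Leaving out mutant replicate 2 gave 0.268 for Dnajb1, 0.154 for Fosb, 0.0632 for Ccnd2, 0.0802 for Ccnd1 and 0.157 for Kdm5d. Fosb had 0.0776 without wild-type replicate 1 and 0.0528 without wild-type replicate 2, and DESeq2 gave it 0.0948. Ier2 had 0.0536 without wild-type replicate 2. A cell cycle call appeared without wild-type replicate 1 (0.0277).

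Camera thus called 12 of 27 lists, 7 up and 5 down. With an estimated correlation 0 were called, and 0 had an unadjusted p below 0.05, while fry called 1, neurons and Schwann cell lineage (adjusted p = 0.0359). That correlation was estimated from only 2 libraries per genotype, so the absence of calls in this setting does not decide whether a list changed. The calls of HoxA, distal limb bud and autopod, erythroid cells, neurons and Schwann cell lineage, and immediate early and heat shock genes were made in each of the 4 fits that left out 1 library. Without mutant replicate 1 camera called 6 lists, and without wild-type replicate 2 it called 7.

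**Figure D2:**
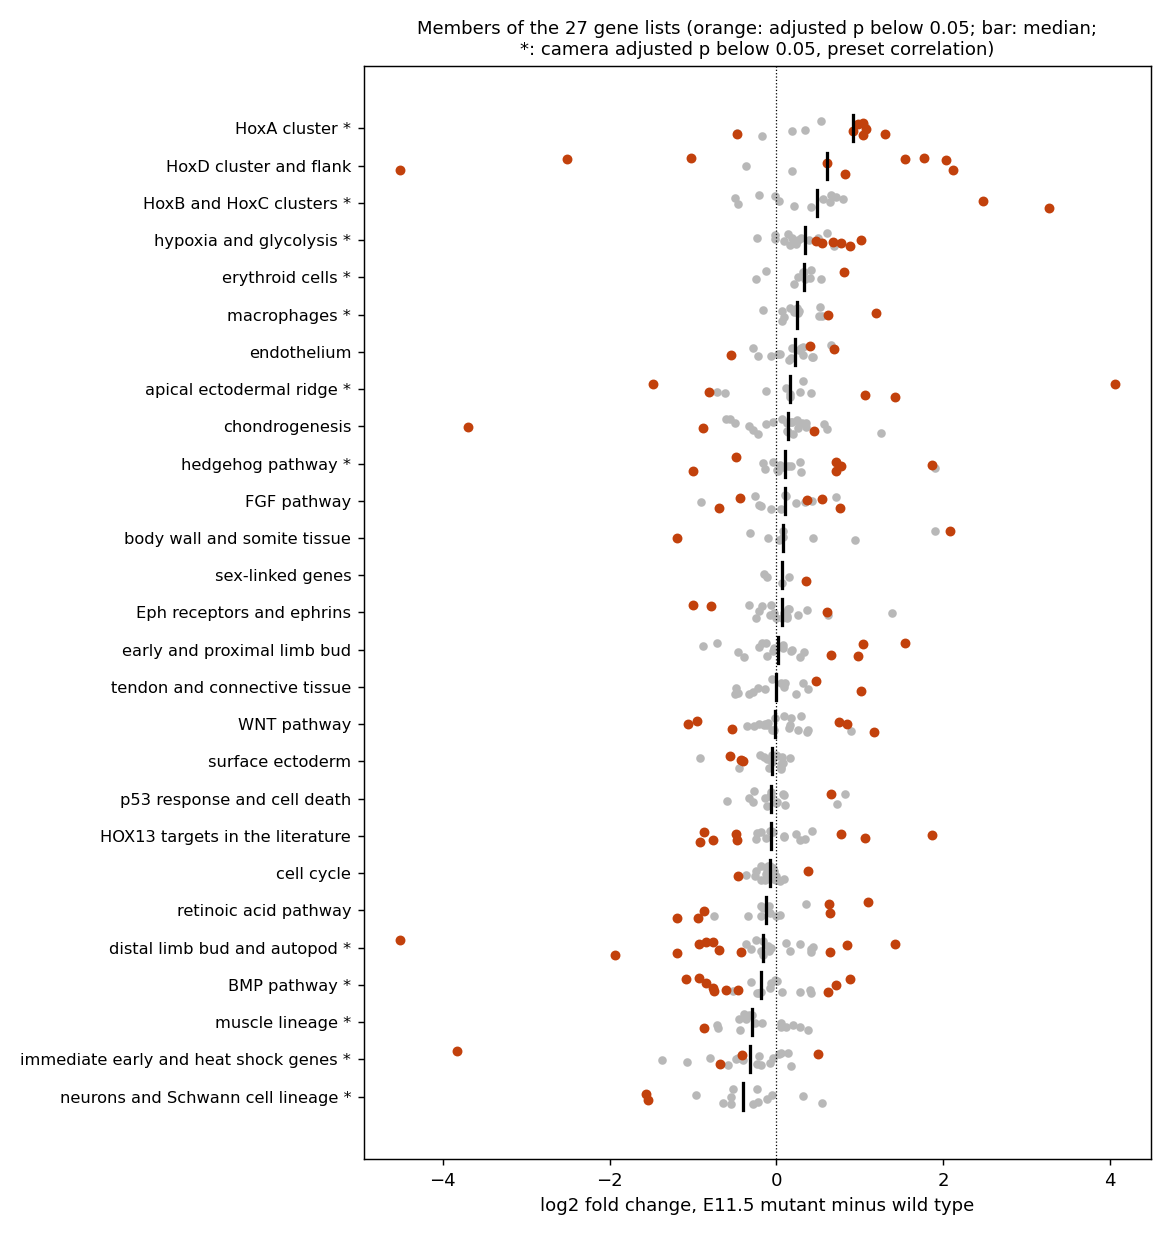
Log2 fold change (mutant minus wild type, E11.5) of the measured members of the 27 gene lists, with a point for each gene, orange where the adjusted p was below 0.05, a black bar at the median and an asterisk where camera with a preset correlation called the list. The lists are ordered by median, from HoxA (0.93) at the top to neurons and Schwann cell lineage (-0.40) at the bottom.

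The E10.5 forelimb bud was then compared with wild-type E11.5 distal tissue, as a view of an earlier bud. Genes of early and proximal limb bud were higher at E10.5: 14 of 20 were at least 2-fold higher than in both wild-type libraries and 1 was lower. Their median log2 difference was 1.84, at percentile 100 of the random lists. Among them Irx3, a homeobox gene of the proximal bud, measured 32.2 CPM against 0.837 ± 0.384 (log2 difference 5.28), Pkdcc, a secreted kinase of skeletal growth, 293 against 8.50 ± 4.78 (5.22), and Meis2, a proximal homeobox gene, 119 against 14.3 ± 3.30 (3.07). Distal, cartilage and muscle genes were lower. In the distal list 8 of 26 were lower and 2 higher (median -0.30, percentile 0.04), with Pax9 at 0.218 CPM against 9.30 ± 0.0749 (-5.21) and Jag1 at 34.1 against 164 ± 9.25 (-2.27). In chondrogenesis 13 of 27 were lower and 2 higher (median -0.88, percentile 0.02), with Col9a2 at -3.49 and Col9a3 at -2.89, and in the muscle lineage 10 of 17 were lower and 2 higher (median -3.11, percentile 0), with Myog, a regulator of muscle differentiation, at -5.88.

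The Hox clusters differed gene by gene. Hoxa13 measured 6.17 CPM at E10.5 against 47.7 ± 1.61 (-2.94) and Hoxd13 63.0 against 240 ± 3.65 (-1.93). HoxA had 2 higher and 3 lower of 13 (median 0.55, percentile 99.92), HoxD 5 and 4 of 12 (0.70, percentile 100) and HoxB with HoxC 11 and 4 of 17 (2.95, percentile 100), with Hoxb5 at 5.30, Hoxb6 at 4.75, Hoxc4 at 4.08 and Hoxc5 at 3.99. Among signalling lists BMP had 0 higher and 9 lower of 23 (median -0.40, percentile 0). The counts were in hedgehog 3 and 0 of 19 (0.34, percentile 99.34), FGF 1 and 3 of 17 (0.25, percentile 94.18), the ridge 4 and 3 of 14 (0.26, percentile 97.87), and HOX13 targets 6 and 4 of 22 (0.24, percentile 95.24). Shh measured 7.83 CPM at E10.5 against 1.72 ± 0.168 (2.17) and Fgf4 5.56 against 0.422 ± 0.0970 (3.63). WNT had 7 higher and 3 lower of 25 (percentile 66.34), retinoic acid 2 and 4 of 16 (percentile 46.3), and Eph receptors with ephrins 3 and 1 of 22 (percentile 43.44). In other lineages, tendon had 0 higher and 6 lower of 16 (-0.65, percentile 0.02; Dcn -3.83), macrophages 0 and 11 of 14 (-1.47, percentile 0.1) and neurons 1 and 6 of 14 (-1.02, percentile 4.98). The same counts were for body wall 7 and 4 of 14 (1.01, percentile 100), erythroid cells 3 and 0 of 11 (0.89, percentile 99.99; Hba-x 2.19), endothelium 3 and 0 of 18 (0.56, percentile 99.98) and surface ectoderm 1 and 2 of 21 (percentile 66.07; Krt14 -2.76). Immediate early and heat shock genes had 6 higher and 1 lower of 20 (0.51, percentile 99.99), cell cycle 0 and 0 of 28 (percentile 68.09), p53 and cell death 0 and 1 of 17 (percentile 73.92), hypoxia and glycolysis 0 and 1 of 20 (percentile 88.29), and sex-linked genes 1 and 3 of 6 (-1.11, percentile 0.01). With library totals in place of TMM the median of all genes shifted to -0.25, and the medians of WNT, Eph, cell cycle, p53, hypoxia and surface ectoderm turned from positive to negative. Each of these medians was smaller than the shift, so the turn follows from the scaling, and their place among the random lists is the percentile given above. The median of retinoic acid genes changed from -0.01 to 0.14 without wild-type replicate 1, and that of Eph genes from 0.02 to -0.09 without wild-type replicate 2.

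In all, 646 of 16738 genes were higher at E10.5 and 2155 were lower, 16.7% of the genes. With library totals these were 412 and 2640, so that 13.5% rather than 23.1% of the differences were higher at E10.5. Without wild-type replicate 1 they were 985 and 2446. Of the lower genes 1713 (79.5%) had under 5 CPM in the E10.5 library and in at least 1 wild-type library, and among the 11054 genes at or above that level, a limit chosen after seeing the data, 434 were higher and 442 lower. The 8 genes furthest above wild type by the naming rule had no count in any E11.5 library. They were Mia3, a protein of secretory export (156 CPM, at least 2430-fold higher), Aida (92.2, at least 1440-fold), Ccdc82 (89.6, at least 1400-fold) and Brox (76.4, at least 1190-fold). Next came the vesicle protein gene Vamp7 (64.0, at least 1000-fold), Disp1, which releases hedgehog ligands (34.3, at least 536-fold), Taf1a (22, at least 344-fold) and Jrkl (18.9, at least 296-fold). In total 20 genes with at least 30 counts at E10.5 had no E11.5 count, and 14 of them had a neighbouring gene in the set. At most 2 did in 1000 random sets. Reads of the 2 stages may therefore have been assigned to genes in different ways, and these folds are uncertain as differences in expression. The 8 on the other side were Tsnax, an RNA-binding protein (0.136 CPM against 125 ± 6.23, log2 difference -9.51), the Y-linked Ube1y1 (0 against 6.59 ± 1.30, at least 161-fold lower), and Kera, a matrix proteoglycan (-7.34). They also included Oaz1, which limits polyamine synthesis (-7.12), Slc6a18 (3 counts, ratio 299, interval 102 to 1450), Col8a1 (-6.84), the T-box gene Tbx22 (2 counts, ratio 272, interval 75 to 2250) and the myosin light chain gene Myl1 (-6.61). These 8 had at most 0.136 CPM at E10.5. Whether their reads were assigned in different ways at the 2 stages was not tested, so their differences are uncertain as well. Among genes with at least 30 counts in every library, a rule chosen after the values were seen, the largest differences were those of Xist (7.56), the RNA that silences an X chromosome, Igdcc3 (5.36), Irx3, Pkdcc and Lin28a, a regulator of early development (4.54), and on the lower side Ttn (-5.94), Actc1 (-5.85) and Myh3 (-5.83), genes of the muscle contractile apparatus, and Miat (-6.07). The E10.5 library also differed in its make-up: Xist measured 198.5 CPM before TMM scaling against 1.0 to 1.4 in the E11.5 libraries, Ddx3y 75.4 against 161.5 to 193.8, and the ribosomal precursor Rn45s 20538.5 against 6319.4 to 8054.1. With 1 library at E10.5 these differences have no replicate check, and they compare libraries that differ in stage, dissected part and strain label. The Xist and Ddx3y values point to E11.5 pools, mutant and wild type, of mostly or only male embryos. For the E10.5 library, which held both RNAs, they point to embryos of both sexes. Sex was not separated from the other differences.

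The last comparison asked whether the genes changed in the mutant lay toward the E10.5 state. The E10.5 library also differs from wild type in dissected part and strain label, so a likeness to it need not be one of stage. Of the 617 genes that rose in the mutant 92 (14.9%) were higher at E10.5, where 3.5% of all genes tested in both comparisons were, and of the 540 that fell 167 (30.9%) were lower at E10.5, where 12.5% were. With the 5 libraries scaled together, Hoxd4 measured 45.8 CPM at E10.5, 51.9 and 47.1 in the mutant libraries and 12.1 ± 0.784 in wild type, and Fgf4 5.56, 7.08 and 6.81, and 0.422 ± 0.0970. Cyp1b1, a cytochrome P450, Hfm1, Styk1, the chemokine gene Cxcl12, Hoxd8 and Pop4, a subunit of ribonuclease P, completed the 8 of smallest adjusted p in this direction. Among the genes that fell and were lower at E10.5, Hoxd13, the splicing factor gene Cwc22, Cmah, which makes a sialic acid, Sulf1, which trims heparan sulfate, Evx2, Jag1, the globin gene Beta-s and the kinase gene Sgk1 led. Evx2 measured 0.368 CPM at E10.5, 0.418 and 0.475 in the mutant libraries and 10.3 ± 0.671 in wild type on this scale. In the opposite directions 68 risen genes were lower at E10.5, among them the calcium channel gene Cacna1e and Col6a5, and 19 fallen genes were higher, among them Nlrp1a and Gstp1.

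Independent lists of these sizes would share 21.9 risen and higher genes, 67.6 fallen and lower genes, 77.2 risen and lower genes and 19.1 fallen and higher genes. Both comparisons use the same wild-type libraries, so part of the excess over independent lists may come from the shared controls. In 20 simulations of an unchanged mutant, with the E10.5 group keeping its own means, 6.66% on average (4.86 to 8.27) of equally many top-ranked risen genes were higher at E10.5. Of the top-ranked fallen genes 20.8% (17.6 to 23.3) were lower. The observed shares were 14.9% and 30.9%, and these simulations were chosen after seeing the data. Across genes, which are not independent replicates, the covariance of both log2 differences was 0.101 against 0.0335 in 20 simulations in which both groups differ from wild type by noise alone, a difference of 0.0675. The correlation was 0.178, against 0.429 (0.404 to 0.455) in the simulations. With mutant set against wild-type replicate 1 and E10.5 against wild-type replicate 2 there were 103 risen and higher genes (43.4 for independent lists) and 174 fallen and lower genes (106.9). In the reverse arrangement there were 132 (55.4) and 181 (149.1), so that the ratio for fallen and lower genes was 1.21 in place of 2.47. Each comparison then rests on only 1 wild-type library. Without wild-type replicate 1 there were 212 risen and higher genes (62.1 for independent lists) and 189 fallen and lower genes (132.4), so that the ratio for the latter was 1.43. Among genes of at least 5 CPM, chosen after seeing the data, they were 60 risen and higher genes (15.1 for independent lists) and 94 fallen and lower genes (16.8).

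**Figure D3:**
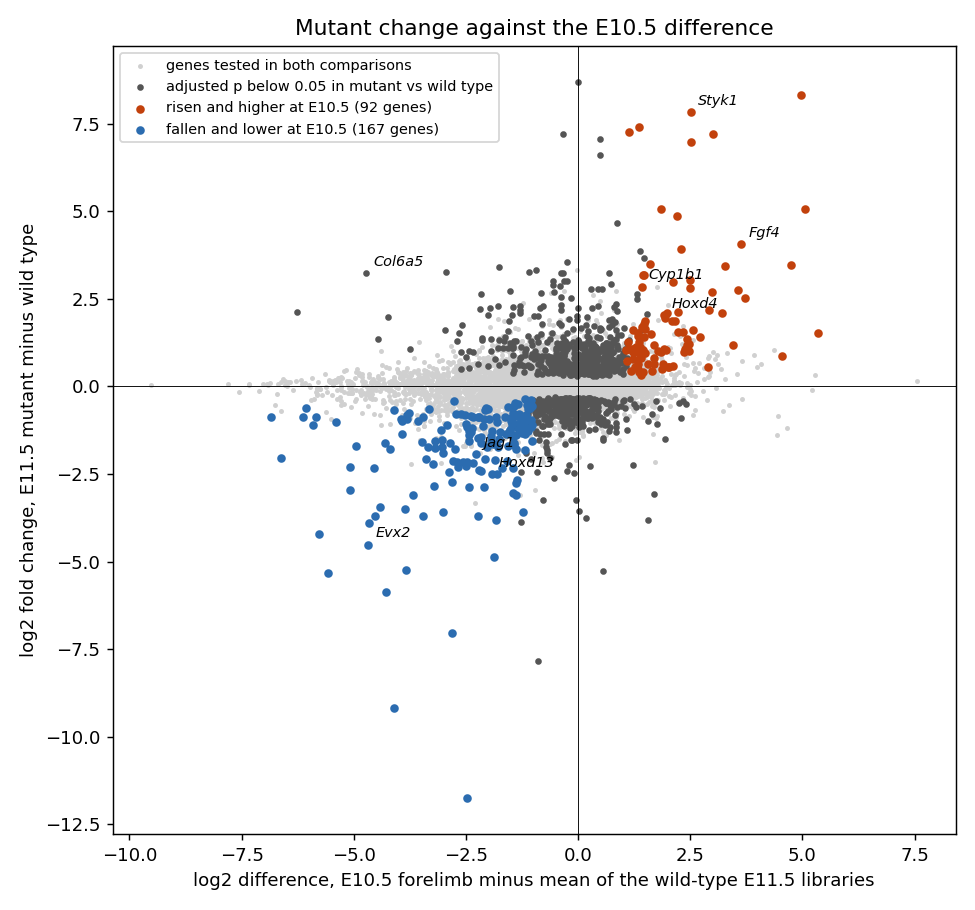
Log2 fold change of each gene between mutant and wild type at E11.5 (vertical) against its log2 difference between E10.5 and the wild-type mean (horizontal), with the 92 risen and higher genes in orange, the 167 fallen and lower genes in blue and other changed genes in dark grey. Values of genes with no count in a group depend on the prior count and mark no exact fold.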

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

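The 1157 genes changed in the mutant became 1762 with no filter, 446 when at least a 2-fold change was required, and between 796 (without mutant replicate 1) and 2018 (without wild type replicate 1) when a library was left out. The replicate numbers of mutant and wild-type libraries were tied to nothing shared in the labels, and the deviations of same-numbered libraries had a correlation of -0.0775. With the replicate block the count was 1252 (676 risen, 576 fallen). With DESeq2 it was 1148, with library totals 945, with a robust fit 1412 and with libraries thinned to the shallowest 1101. Among calls shared with these fits 0 reversed. Named genes of the mutant comparison were followed with DESeq2, DESeq2's size factors, no filter, the replicate block, thinned libraries and each library left out. Over these fits 1020 values stayed on their side of the threshold, 43 lost and 53 gained a call. Of the lists, 12 were called by camera, 0 with an estimated correlation, 1 by fry, 11 with the replicate block, where the apical ectodermal ridge list had an adjusted p of 0.0835 (the block gave Foxc2 0.0516), and 6 (without mutant replicate 1) to 14 (without mutant replicate 2) with a library left out. The 2801 genes beyond 2-fold at E10.5 became 4907 at a fold of 1.5, 1088 at a fold of 4, 876 among genes of at least 5 CPM, and 3431 (985 higher, 2446 lower) without wild type replicate 1 and 3681 (872 higher, 2809 lower) without wild type replicate 2. The 259 concordant genes became 394 at a fold of 1.5, 154 at 5 CPM or more, and 200 (without mutant replicate 1) to 401 (without wild type replicate 1). These counts follow from the stricter or looser limits where a limit was changed. For libraries left out the cause was not tested.

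The test's direction or the median of 7 uncalled lists turned when a library was left out. The median of Eph receptors and ephrins was 0.043 without mutant replicate 1, 0.124 without mutant replicate 2 and -0.0385 without wild type replicate 2. That of the WNT pathway was 0.0537, 0.0637 and -0.114 in the same fits and 0.0532 without wild type replicate 1. For HOX13 targets in the literature it was 0.0168 and 0.00264 without mutant replicate 1 and 2, for early and proximal limb bud -0.0921 without wild type replicate 2, and for tendon and connective tissue 0.0286 and 0.0729 without wild type replicate 1 and 2. For p53 response and cell death it was -0.0952 without wild type replicate 1 and 0.0215 without wild type replicate 2. For sex-linked genes it was 0.0435 without mutant replicate 1, -0.0761 without mutant replicate 2, -0.0194 without wild type replicate 1 and -0.0495 without wild type replicate 2. The cause was not tested.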

Other observations

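The gene families and single genes of the next paragraphs, the test on proximal tissue, the simulated and split medians for delay and both tests on genes without counts were chosen after seeing the data. The predictions on linked haplotypes, local regulation, shared wild-type libraries and overall delay were written before the data were examined.

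Of 62 replication-dependent histone genes, which are transcribed in S phase, 17 fell and 2 rose in the mutant, with a median log2 fold change of -0.26 and 52 below 0. At E10.5 26 of 63 were higher and 0 lower than in wild type (median 0.95). Without wild-type replicate 1 there were 39 fallen histone genes, and without mutant replicate 2 there were 10. Without wild-type replicate 2 there were 15 fallen and 4 risen, with a median of -0.10. The family was not tested as a set. Of 41 collagen genes 9 rose and 1 fell in the mutant (median 0.11), while at E10.5 13 of 42 were lower and 1 higher (median -0.63). Without wild-type replicate 1 there were 17 risen collagen genes (median 0.30), and without wild-type replicate 2 there were 8 risen and 6 fallen (median 0.05). Of 43 protocadherin beta and gamma genes, cell surface molecules encoded in clusters, 1 rose and 0 fell (median 0.18), and 12 rose without wild-type replicate 1. Their median was 0.41 without wild-type replicate 1, 0.31 without mutant replicate 1 and 0.07 without wild-type replicate 2. Of 76 cytosolic ribosomal protein genes 0 changed, while 8 rose and 8 fell without wild-type replicate 1 and 4 rose without wild-type replicate 2.

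A few genes had counts in one genotype only. BC049730 had 365 and 469 counts in the wild-type libraries and 0 in both mutant libraries, at least 135-fold lower, and the Y-linked Usp9y had 86 and 49 against 0, at least 22.7-fold lower. Cldn13, a claudin gene, had 44 and 39 counts in the mutant libraries and 0 in wild type, at least 11.6-fold higher, and Klk1b22, a kallikrein gene, 49 and 57 against 0, at least 15-fold higher. Other Y-linked genes did not follow Usp9y: Ddx3y had a log2 fold change of -0.14 with an adjusted p of 0.472 (-0.03 without mutant replicate 1, -0.26 without mutant replicate 2) and Uty 0.07 with 0.733. The E11.5 libraries were labelled as a mixed background, and strain differences between mutant and wild-type pools were not tested. Such differences were not separated from the effect of the targeted alleles, in these genes or in the other calls.

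Of the 80 tested genes nearest to Hoxd13 and Hoxa13, 20 on each side and without the listed Hox genes, 12 changed in the mutant (15%), against 24 of the 320 further out (7.5%). For local regulation at the targeted loci the odds ratio of near against further genes was 2.17 (95% interval 0.94 to 4.78, one-sided Fisher p = 0.0351). Of the 12 changed genes 9 lay within 20 tested genes of Hoxd13, among them Dlx2, Itga6, Pdk1 and Cwc22. Around Hoxa13 3 of 40 changed (7.5%), against 7% of genes elsewhere. Unlisted transcripts beside the targeted genes stayed in the set. Of these, Mira and 5730457N03Rik near Hoxa13 and 1700109F18Rik near Hoxd13 were among the 12 changed genes. The excess near the loci was predicted for a local effect, but a short linked haplotype would give it too, so the test cannot tell them apart. The odds ratio of near against further genes was 1.71 without mutant replicate 1 and 2.67 without mutant replicate 2. It was 1.82 without wild-type replicate 1 and 1.78 without wild-type replicate 2. For a linked haplotype carried with the alleles, the odds ratio of the further genes against all others was 1.07 (0.672 to 1.63, one-sided Fisher p = 0.406), which leaves it open. By locus this odds ratio was 1.47 (0.814 to 2.48) around Hoxd13 and 0.695 (0.294 to 1.41) around Hoxa13. Fisher tests treat neighbouring genes as independent, and an effect of the inserted cassettes themselves was not tested.

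Genes that rose in the mutant were more often higher at E10.5. The strain label differed between E10.5 and E11.5 as well, and its part in this overlap was not tested. Shared wild-type libraries as the whole cause would leave no covariance with the controls split if genes varied independently. The split covariances were 0.0866 and 0.0222 (correlations 0.141 and 0.0345), above the highest simulated values of 0.00344 and 0.00214. The simulated genes varied independently, while real wild-type pools may differ in many genes together, so the test cannot decide this. More proximal tissue in the mutant dissection would have raised all proximal markers, and the median share of E10.5-like tissue that 7 of them needed was -0.0025, against 0.577 for the 92 overlap genes, which were selected as risen and higher. The markers' share argues against more proximal tissue as a sole cause, although Hoxd9 (0.479) and Zbtb16 (0.232) needed larger shares. The 0.577 follows in part from the selection. All shares assume that the E10.5 bud stands in for E11.5 proximal tissue, which was not measured. An overall delay is left open: the median mutant log2 fold change was 0.135 for genes higher at E10.5 and -0.0549 for lower ones, against 0.0405 (0.0215 to 0.053) and -0.0372 (-0.0474 to -0.0245) with a simulated unchanged mutant, 0.0886 and -0.0956 at 5 CPM or more, and 0.039 and -0.106 or 0.136 and 0.171 with the controls split.

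In total 20 genes with at least 30 counts at E10.5 had no count in any E11.5 library, such as Mia3, Aida, Brox, Disp1 and Taf1a on chromosome 1. Of these 14 had a neighbouring gene in the set, against at most 2 in 1000 random sets, which is consistent with reads of the 2 stages having been assigned to genes in different ways. Genes silent in E11.5 tissue of mixed background remain a possibility that was not decided: the E10.5 median of 8.48 CPM, against 16 CPM for genes tested, does not bear on the level at E11.5. The opposite pattern was present as well, with 27 genes of at least 100 counts in each E11.5 library and at most 2 at E10.5. Folds of such genes are therefore uncertain. The 20 genes were counted in the E10.5 library, labelled CD1, and CD1 was also part of the mixed E11.5 background. A deletion would have to be absent at E10.5 yet carried on every copy in all 4 E11.5 pools, at loci on several chromosomes. This argues against deletions in the strains as the cause for these 20 genes. For the 27 genes of the opposite pattern deletions were not tested.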
